A study of Rattus norvegicus with 24 samples.

How the data were processed

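The samples were left ventricles of Dahl salt-sensitive rats, an inbred strain that becomes hypertensive on a high salt diet. Total RNA was hybridised to an Affymetrix rat expression array, which measures each transcript with 1 or more probe sets. Per the labels, rats arrived at 5 weeks of age and treatment began at 6 weeks of age. The exercised rats ran daily on a treadmill for 6 weeks, with 3 weeks of increasing load and then a steady load of 16 m/min on an incline of 5 degrees for 90 minutes a day. The high salt rats received chow with 6% NaCl, and the controls were sedentary rats of matched age on normal chow. Groups and replicate numbers were taken from the sample titles, which give 3, 6 or 15 weeks for each array. The titles of the 3 arrays numbered 1 at 6 weeks carry a second number, which the labels do not explain. The labels used here do not say from when these weeks were counted. The titles list 24 columns in 8 groups of 3: control, exercise and high salt at 3 and 6 weeks, and control and high salt at 15 weeks. The labels do not say that each array came from a separate animal, so p-values measure only the spread between these arrays.

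The deposited table held 1 linear intensity per probe set and array, for 8799 probe sets. The summary method, background step and software of the authors are not given in the sources used here. The mean of each column after trimming 2% lay between 500.767 and 501.021, so the deposited intensities had already been scaled to a common level and were used as they stood. No detection calls were used here, and the number of arrays limits the precision of every value.

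Of the 24 columns, 4 held 2 arrays deposited under labels of different groups. The columns of exercise at 3 weeks numbered 2 and 3 were identical in all 8799 values to those of control at 3 weeks numbered 2 and 3, while other pairs of columns shared at most 31 identical values. The table therefore held 22 distinct arrays. An array cannot belong to both groups, and its group was not inferred from its values, so both were left out and 20 arrays entered the fit. That left 1 control and 1 exercise array at 3 weeks. The design fixed before the data were examined used all 24 columns; leaving these out was decided after the identity was seen. A total of 4 readings were run: both arrays left out, both as controls, both as exercise, and all 24 columns as deposited, which is the design as first written. Where their counts differ by more than a little they stand in the section on processing.

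Control probe sets, 59 in number, were left out, leaving 8740. Intensities were transformed as log2(value + 40), where the pseudocount is the 25th percentile of all values rounded to 1 digit. Fold changes are on this scale, which understates the change of dim genes. Probe sets with a mean below the 25th percentile were not tested, which left 6555. A linear model with 1 mean per group was fitted to all 20 arrays together with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom, followed by empirical Bayes moderation with an intensity trend. A group with 1 array is assumed to vary like the others. Adjusted p-values are limma's, corrected by the Benjamini-Hochberg method over the 6555 probe sets, and a probe set was called at an adjusted p under 0.05. Without any change, a share of 0.05 of the tested probe sets is expected at an unadjusted p under 0.05. The counts given for exercise and high salt against control at 3 weeks, and for the controls over time, lie below that share. Of the 13 comparisons, 5 set a treatment against the controls of 1 week, and the rest compared treatments, combined weeks, or tested differences between weeks. The probe annotation gave 1 gene symbol for 7018 probe sets and several for 308; another 1473 had no entry and are unnamed here. The tested probe sets covered 3827 genes. No coordinates are given because the array names no genome build.

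The 25 gene lists were fixed before the data were examined, 7 of them for other cell types that heart tissue can hold. Each gene was represented by its brightest tested probe set. An older symbol was used only where the listed name was not itself a current symbol. Lists were tested with camera in limma, which asks whether the members shift relative to all other genes, at a preset correlation of 0.01 and again with the correlation estimated from the residuals. List p-values were adjusted over the lists within a comparison. List values with the GAPDH ratio as a covariate are given at the preset correlation only. The fry test, which asks whether the members move on balance in 1 direction without comparing them with other genes, was run beside it.

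Genes were named by a rule set beforehand: among called probe sets with 1 symbol and no overlap between the groups in any week compared, the 10 largest changes in each direction; with fewer than 5 called probe sets, the 5 smallest p-values in each direction; up to 4 members with the smallest p from each list; and always Nppa, Nppb, Myh6, Myh7, Acta1 and Atp2a2. This part of the rule was applied to the brightest probe set of each gene. For differences between weeks, the 5 largest called changes in each direction were named, at any probe set with 1 symbol. Genes outside this rule are said to be so. Where other probe sets of a named gene existed, their sign was checked.

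RNA integrity was read from the control probe sets for the 3' and 5' ends of GAPDH, whose ratio rises as RNA is degraded. The model was checked on simulated data, with 200 probe sets changed by known folds. It recovered 60% of the 2-fold and 95% of the 4-fold changes for exercise against control at 6 weeks, 51% and 92% for high salt at 6 weeks, and 58% and 95% for high salt at 15 weeks. At 3 weeks it recovered 11% and 66% for exercise and 19% and 76% for high salt, and 43% and 92% for high salt against exercise at 6 weeks. Alternatives chosen before the data were examined were quantile normalization, pseudocounts of 13 and 130, no filter, a filter at the 50th percentile, no intensity trend, a fit to the compared groups alone, a block for the replicate number, array weights, the mean of all probe sets of a gene for lists, and leaving out each array in turn. Alternatives added after seeing the data were the readings of the 2 arrays, the GAPDH ratio on the log2 scale as a covariate, the controls of 3 and 15 weeks in place of those of 6 weeks, and all 4 distinct arrays of 3 weeks without salt as the reference for high salt at 3 weeks. Figures were drawn with matplotlib.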

Results

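Left ventricular transcripts were measured in Dahl salt-sensitive rats that were exercised on a treadmill, fed a high salt diet or kept as sedentary controls. The series set exercise, a model of physiologic cardiac hypertrophy, beside high salt, a model of pathologic hypertrophy. After 2 arrays deposited under both the control and the exercise label of 3 weeks were left out, there were 1 control, 1 exercise and 3 high salt arrays at 3 weeks. At 6 weeks there were 3 arrays each of control, exercise and high salt, and at 15 weeks 3 each of control and high salt. Values are deposited intensities as mean ± SD, and changes are log2 fold changes ± SE from limma.

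The 6-week controls differed from other arrays in RNA integrity. Their GAPDH 3' to 5' ratios were 1.58, 2.48 and 3.99. The 15-week controls had ratios of 1.09, 1.52 and 1.58, and the 16 distinct arrays of all other groups ranged from 0.989 to 1.18. For beta-actin the same ratio was 1.98, 3.29 and 2.73 in the 6-week controls and averaged 1.30 ± 0.22 in the 19 other distinct arrays. For hexokinase it was 3.00, 8.35 and 11.06 in the 6-week controls and 1.48 to 3.16 in the other distinct arrays. These ratios stand beside every comparison with the 6-week controls below.

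**Figure D1:**
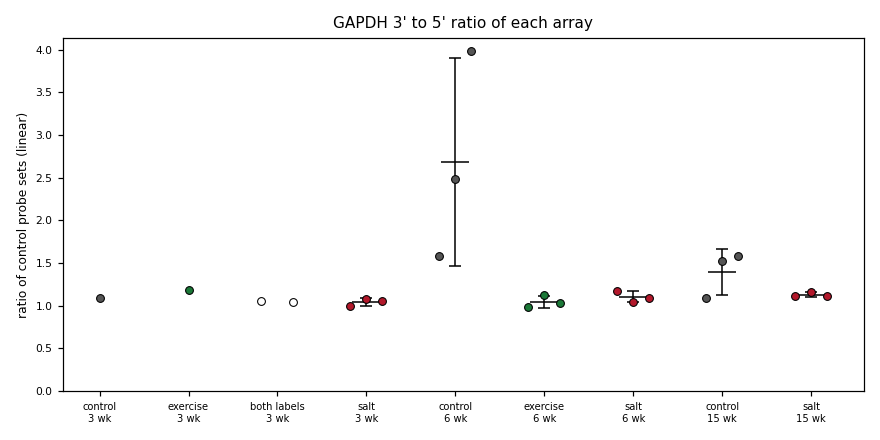
GAPDH 3' to 5' ratio (linear axis, from 0) of each of the 22 distinct arrays by group, points being arrays and bars mean ± SD where a group has 3 arrays; open points are the 2 arrays carrying both labels. The 6-week controls, at 1.58 to 3.99, reach the highest ratios.

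The comparison of high salt with control at 15 weeks asked how the ventricle differed late on the diet. Nppa, which encodes atrial natriuretic peptide and is a marker of ventricular load, rose by 2.41 ± 0.30, from 4506 ± 1233 to 23511 ± 2377 (n = 3 each; adjusted p = 6.1e-05). Acta1, skeletal alpha-actin of the fetal ventricle, rose by 1.07 ± 0.18. Nppb, encoding B-type natriuretic peptide, was at 2999 ± 923 against 3799 ± 640 in controls, a difference that did not pass the test (adjusted p = 0.52). At their brightest probe sets Myh6, Myh7 and Atp2a2 did not pass either, with -0.33 ± 0.19, 0.0070 ± 0.23 and -0.16 ± 0.20, while another probe set of Atp2a2 fell by -0.72 ± 0.18 (adjusted p = 0.0166). Alox15, a lipoxygenase, had the smallest p: its intensity was 6997 ± 635 against 443.2 ± 28.4, a rise of 3.86 ± 0.21 (adjusted p = 5.1e-10). The largest rises also included Reg3b (5.40 ± 0.96), Pdk4, a kinase that restrains pyruvate oxidation (3.55 ± 0.53), Pcp4 (2.95 ± 0.52) and Spp1, encoding osteopontin (2.85 ± 0.44). Akip1, Pdlim5 and Gpd1 rose by 1.99 to 2.23.

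Several collagen genes fell in the same hearts. Col3a1 fell from 5264 ± 915 to 688.8 ± 462, a change of -3.04 ± 0.32 (adjusted p = 7.7e-06), Col15a1 by -1.77 ± 0.29 and Col1a2, of type I collagen, by -1.59 ± 0.28. Serpinh1, a chaperone of collagen folding, changed by -1.82 ± 0.28. Of 40 measured genes of the extracellular matrix and fibrosis list, 11 fell and 1, Spp1, rose (15 and 1 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.00028; adjusted p = 0.65 with an estimated correlation). The GAPDH ratio averaged 1.40 ± 0.27 in these controls and 1.13 ± 0.03 in the salt arrays. The same ratio for beta-actin went the other way, at 1.32 ± 0.21 in the controls and 1.52 ± 0.18 in the salt arrays. For hexokinase it was 2.02, 3.02 and 2.35 in the controls and 2.29, 1.80 and 2.19 in the salt arrays. Among the other large falls were the clock gene Dbp (-3.12 ± 0.56), Nmrk2 (-2.63 ± 0.27), the G1 cyclin Ccnd1 (-2.18 ± 0.27), the clock repressor Nr1d1 (-2.07 ± 0.27), Tuba4a (-1.96 ± 0.32) and Vtn, encoding vitronectin (-1.90 ± 0.20). Of 4 other probe sets of Ccnd1, 2 had the opposite sign.

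Of 37 members of the inflammation and leukocytes list, 5 fell and 1 rose (6 and 2 adjusted over the list alone), with a median of 0.01, a mean of -0.13 and a list test that pointed down without passing (adjusted p = 0.532). Those that fell included RT1-Da (-1.90 ± 0.28), Cd74 (-0.93 ± 0.17) and RT1-Bb (-1.04 ± 0.26). Of 30 antioxidant genes, 5 rose, including the heme oxygenase Hmox1 (1.58 ± 0.29) and Mgst1 (1.37 ± 0.32), and 1 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.0796). Of 21 glycolysis genes, 6 fell and 3 rose (6 and 3 adjusted over the list alone), with a median of 0.06, a mean of -0.12 and a list test pointing down (adjusted p = 0.783). The insulin-responsive glucose transporter gene Slc2a4 fell by -0.91 ± 0.21, while Slc2a1, encoding the basal transporter, rose by 0.75 ± 0.22. Transcripts of red blood cells rose as a group: 4 of 7 rose (6 adjusted over the list alone), with a median of 0.70 (adjusted p = 5.8e-08; adjusted p = 0.0060 with an estimated correlation). Alas2, which starts erythroid heme synthesis, rose by 2.16 ± 0.25 and Slc4a1, the band 3 anion exchanger, by 1.94 ± 0.20, with 1 of its 2 other probe sets on the opposite side. Other lists did not pass. Their medians were 0.15 for fetal and stress genes, 0.01 for fatty acid oxidation, -0.18 for oxidative phosphorylation and citric acid cycle genes and 0.02 for calcium handling. With the GAPDH ratio as a covariate the oxidative phosphorylation (median -0.35, adjusted p = 0.00020), heat shock (-0.25, 0.035) and clock (-0.61, 0.035) lists passed downward at the preset correlation, beside the matrix list (-0.31, 0.0035) and the red blood cell list upward (0.78, 4.4e-08).

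In all, 214 probe sets rose and 255 fell of 6555. Leaving out the control numbered 2 gave 212 calls, without the control numbered 3 there were 281 and without the salt array numbered 1 there were 294. With the GAPDH ratio as a covariate there were 397 calls, 354 of them among the 469. The replicate block gave 250, a fit of only the compared groups 266 and array weights 1036.

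**Figure D2:**
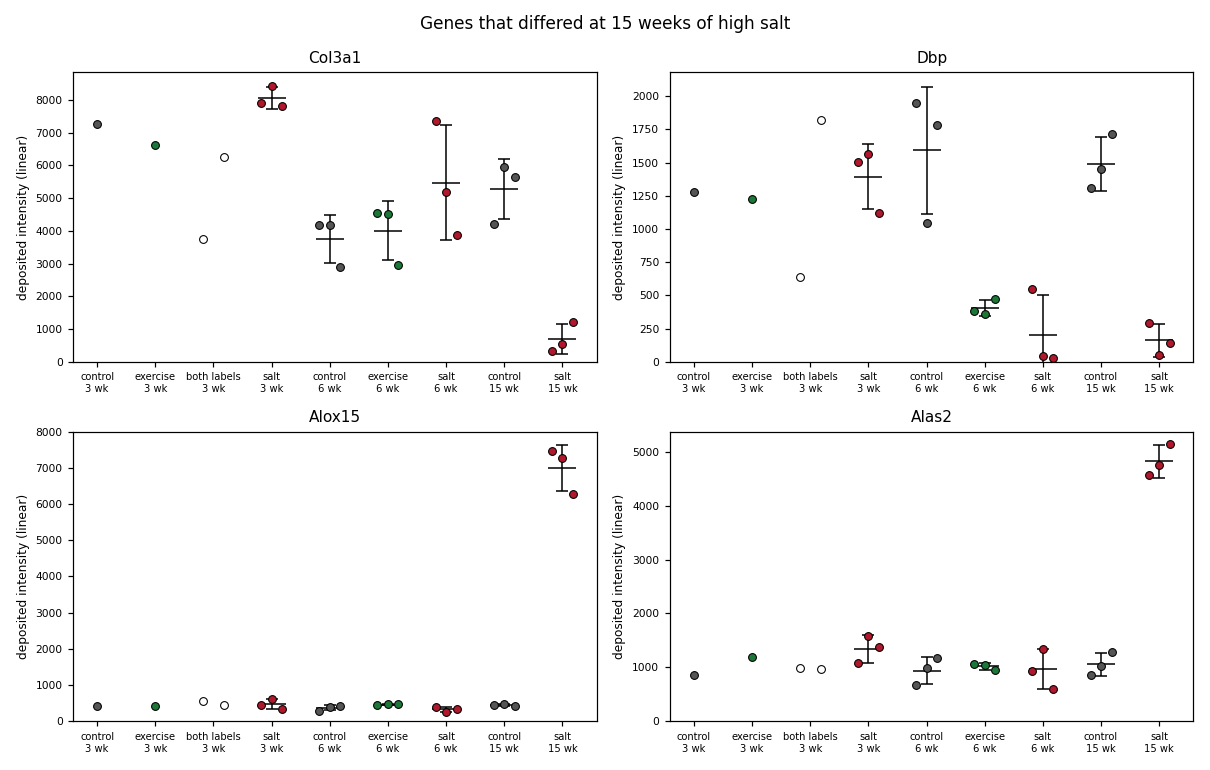
Deposited intensity (linear axes, from 0) of Col3a1, Dbp, Alox15 and Alas2 in each distinct array by group; points are arrays, bars mean ± SD for groups of 3, and open points the 2 arrays carrying both labels. The 3 high salt arrays of 15 weeks average 6997 for Alox15 and 4818 for Alas2, above every other array, and 688.8 for Col3a1, below every other array.

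High salt was compared with control at 6 weeks to give an earlier stage of the same diet. Nppa rose by 2.41 ± 0.30, from 2019.9 ± 1025 to 9999 ± 208 (n = 3 each; adjusted p = 0.00013), Nppb by 1.91 ± 0.28 and Acta1 by 1.07 ± 0.18. Ankrd1, a stretch-responsive cofactor, rose by 0.75 ± 0.20. Probe sets of the myosin and calcium pump genes differed. At the brightest ones Myh6 (0.32 ± 0.19) and Myh7 (0.51 ± 0.23) did not pass and Atp2a2 rose by 0.65 ± 0.20. Other probe sets of Myh6 rose by 2.25 ± 0.43 and 1.78 ± 0.37 and another of Myh7 by 1.01 ± 0.29, and 1 of Atp2a2 fell by -0.97 ± 0.18. Of 15 fetal and stress genes 6 rose and 3 fell, the same numbers adjusted over the list alone, with a median of 0.20 (adjusted p = 0.0046; adjusted p = 0.10 with an estimated correlation). The 3 that fell were Tagln, Acta2 and Ace, the first 2 being smooth muscle genes. Gja1, encoding connexin 43, rose by 3.26 ± 0.46, and Hsp90b1, a chaperone of the endoplasmic reticulum, by 1.18 ± 0.17. Other large rises were Fat1 (2.56 ± 0.38), Hand2 (2.48 ± 0.30), Aldoa (2.30 ± 0.41) and Egln3 (2.21 ± 0.32).

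Some genes of mitochondrial metabolism rose relative to these controls. Of 30 fatty acid oxidation genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), led by Pdk4 (3.78 ± 0.53), Acot2 (2.77 ± 0.45), the fatty acid carrier Cd36 (2.51 ± 0.44) and Hadhb (1.95 ± 0.35). These 4 were at 1.86, 0.93, 0.81 and 0.37 with the GAPDH ratio as a covariate, none of them called, and against the controls of 3 and 15 weeks at 2.76, 1.07, 1.41 and 0.96, where Pdk4 alone was called. Of 45 oxidative phosphorylation and citric acid cycle genes 8 rose (9 adjusted over the list alone), among them Vdac1 (2.73 ± 0.44) and Ndufs1 (2.20 ± 0.43), at 0.68 and 0.98 with the covariate and 0.93 and 1.07 against those controls without passing. Both list calls were lost with an estimated correlation, at an adjusted p = 0.32 with an estimated correlation for fatty acid oxidation and 0.34 for oxidative phosphorylation. With the GAPDH ratio as a covariate both list medians changed sign, to -0.31 each, the oxidative list passing downward (adjusted p = 0.0189) and the fatty acid list not (0.405), and those of the sarcomere, heat shock, antioxidant and fetal lists to -0.081, -0.082, -0.14 and -0.037. The matrix (median 0.38, adjusted p = 9.5e-05) and inflammation (0.25, 0.0016) lists passed upward and the clock list (-0.41, 0.021) downward with that covariate at the preset correlation. The heat shock, antioxidant, sarcomere and atrial myocyte lists passed at the preset correlation, with medians of 0.17, 0.13, 0.30 and 0.02. Their adjusted p with an estimated correlation was 0.32, 0.32, 0.35 and 0.32. The atrial list holds Nppa, which with Pam made up the 2 members that rose.

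The clock gene Dbp fell by -3.45 ± 0.56, with intensities of 545.3, 39.5 and 25.5 against 1593 ± 479.8 in controls. Nr1d1, Nr1d2 and Per2 fell by -1.34 to -1.05 and Bmal1, which peaks in the opposite phase, rose by 1.65 ± 0.52. Of 9 clock genes 4 fell and 1 rose, as they did adjusted over the list alone (list adjusted p = 0.19). Of 15 cell death genes 4 fell, such as Ddit3 (-1.07 ± 0.23) and Casp2 (-1.59 ± 0.38, both its other probe sets having the opposite sign), and 5 fell adjusted over the list alone. Igf1 fell by -1.28 ± 0.26 and the insulin receptor gene Insr rose by 1.07 ± 0.30 within the growth factor and exercise signalling list, where 3 of 36 rose and 3 fell, as they did adjusted over the list alone. Lcat, Prickle2, Camk2n1 and Fam219b fell by -1.94 to -1.76, and Epb41, Papss2, Mpzl1, Scn7a and Rbm39 by -1.69 to -1.62.

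In all, 434 probe sets rose and 505 fell for high salt against control at 6 weeks. The median of all probe sets was -0.15, and -0.04 after quantile normalization, under which 523 rose and 407 fell. With the GAPDH ratio as a covariate 13 were called. Of the 939, 850 kept their sign with it, the median change in the direction of the call went from 1.01 to 0.54, and the median SE over all probe sets from 0.26 to 0.42. The replicate block gave 561 calls, a fit of only the compared groups 384 and array weights 1811. Against the controls of 3 and 15 weeks 22 were called, all of them among the 939. Acta1 and 3 of 4 probe sets of Nppa were called against either set of controls and with the covariate. Without the controls numbered 1, 2 and 3 there were 1225, 524 and 456 calls, and without the salt arrays numbered 2 and 3 there were 591 and 502.

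Exercise was compared with control at 6 weeks. Pdk4 rose by 4.16 ± 0.53, from 55.7 ± 52.4 to 1539 ± 228 (n = 3 each; adjusted p = 0.00079). It was at 2.12 ± 0.76 with the GAPDH ratio as a covariate (adjusted p = 0.588) and at 3.14 ± 0.49 against the controls of 3 and 15 weeks (adjusted p = 0.0081). Other genes of fatty acid handling rose with it: Acot2 (2.91 ± 0.45), Cd36 (2.29 ± 0.44) and the uncoupling protein gene Ucp3 (1.24 ± 0.25). None of these 3 was called either way, with 0.96, 0.47 and 1.29 with the covariate and 1.21, 1.18 and 1.002 against those controls. In the fatty acid oxidation list 6 of 30 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.36 (adjusted p = 1.3e-10; adjusted p = 0.36 with an estimated correlation). Of 45 oxidative phosphorylation and citric acid cycle genes 6 rose (9 adjusted over the list alone), including Vdac1 (2.82 ± 0.44), Ndufs1 (2.02 ± 0.43) and the citrate synthase gene Cs (1.76 ± 0.42), with an adjusted p = 0.57 with an estimated correlation. These 3 were at 0.64, 0.73 and 0.23 with the covariate and at 1.02, 0.89 and 0.89 against those controls, without passing. With the GAPDH ratio as a covariate, at the preset correlation, the medians of the fatty acid and oxidative lists were -0.072 (adjusted p = 0.573) and -0.43 (adjusted p = 1.0e-06). The oxidative list passed there in the opposite direction, and no estimated correlation is given for it with the covariate. The inflammation list passed upward with it (median 0.27, adjusted p = 0.0022) and the sarcomere (-0.39, 0.0044) and clock (-0.56, 0.047) lists downward. The oxidative median was -0.077 against the controls of 3 and 15 weeks.

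Nppa rose by 1.19 ± 0.30, from 2019.9 ± 1025 to 4516 ± 1688 (adjusted p = 0.019). Against the controls of 3 and 15 weeks Nppa was at 0.13 ± 0.28 (adjusted p = 0.966), and with the GAPDH ratio as a covariate at 0.82 ± 0.52 (adjusted p = 0.799). At their brightest probe sets Nppb, Acta1, Myh6, Myh7 and Atp2a2 did not pass, with changes of 0.18 ± 0.28, 0.13 ± 0.18, -0.13 ± 0.19, -0.02 ± 0.23 and 0.02 ± 0.20. Both other probe sets of Myh6 rose, by 2.09 ± 0.43 and 1.60 ± 0.37 (adjusted p = 0.0053 and 0.011), and another of Atp2a2 fell by -0.65 ± 0.18 (adjusted p = 0.027). Of 15 fetal and stress genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), the rises being Nppa and Des, which encodes desmin and was at -0.83 with that covariate. Calcium handling genes that rose were Pln, encoding phospholamban (1.66 ± 0.33), Casq2 (1.37 ± 0.30), Fkbp1a (1.04 ± 0.27) and Ryr2 (1.58 ± 0.48), 4 of 24 members, 4 also adjusted over the list alone. Of 30 antioxidant genes 3 rose, such as Prdx3 (1.49 ± 0.34), and 7 rose adjusted over the list alone (list adjusted p = 0.36 with an estimated correlation). Of 40 matrix genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.0023; adjusted p = 0.57 with an estimated correlation) that was 0.055 with the GAPDH ratio as a covariate. With that covariate the antioxidant median was -0.012, Pln was at -0.18, Prdx3 at -0.41 and Fstl1 at 0.19, and against the controls of 3 and 15 weeks Myh11 was at 0.21. Of 39 ribosomal protein genes 6 fell, also 6 adjusted over the list alone (adjusted p = 0.67 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, fell by -1.51 ± 0.31, and Nr1d1 by -1.16 ± 0.27. The smooth muscle genes Tagln, Acta2 and Myh11 fell by -1.43 to -0.95, and 3 of 9 members of that list fell and 1 rose, the same adjusted over the list alone. Dlgap4 (-2.29 ± 0.43), Lcat (-2.05 ± 0.32) and Fstl1 (-1.80 ± 0.43) were the largest falls, and Gstk1 (3.39 ± 0.72), Fdft1 (2.86 ± 0.57), Hand2 (2.26 ± 0.30) and Ctsc (1.89 ± 0.33) were among the largest rises.

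In all, 293 probe sets rose and 220 fell for exercise against control at 6 weeks, and the median of all probe sets was -0.12. No probe set was called by limma with the GAPDH ratio as a covariate. Over the 513 called, the median change in the direction of the call went from 1.09 to 0.45, and the median SE over all probe sets from 0.26 to 0.44. Against the controls of 3 and 15 weeks 3 probe sets were called, for Pdk4 and Nr1d1, with 543 at an unadjusted p under 0.05. Those controls were 1 array of 3 weeks and 3 of 15 weeks, the latter with GAPDH ratios of 1.09, 1.52 and 1.58. Nr1d1 was at 639.6 in the 3-week control, 1955.5 to 2484.9 in the 15-week controls and 215 to 340.8 with exercise at 6 weeks. Leaving out the 6-week controls numbered 1, 2 and 3 gave 851, 246 and 210 calls, and leaving out the exercise arrays numbered 2 and 3 gave 249 and 266. With all 24 columns as deposited there were 772, with the replicate block 240, with only the compared groups fitted 255 and with array weights 1720.

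High salt and exercise were compared directly at 6 weeks, which does not involve the controls. Nppb was higher with high salt, at 6999 ± 1089.8 against 2073 ± 271, a difference of 1.73 ± 0.28 (n = 3 each; adjusted p = 0.030). It was the 1 probe set called, with 466 at an unadjusted p under 0.05. Acta1 (0.95 ± 0.18), Hspb1 (0.98 ± 0.20), Ankrd1 (0.92 ± 0.20) and Nppa (1.22 ± 0.30) did not pass, with adjusted p-values of 0.090 to 0.20. As a group the fetal and stress genes were higher with salt: 1 of 15 passed (4 adjusted over the list alone), with a median of 0.23 (adjusted p = 1.2e-06; adjusted p = 0.0024 with an estimated correlation). The matrix (median 0.29), sarcomere (0.43), heat shock (0.11), immediate early (0.26), oxidative phosphorylation (0.10) and ribosomal protein (0.11) lists passed at the preset correlation. None of those 6 passed with an estimated correlation, their adjusted p being 0.27 to 0.772. Under quantile normalization the oxidative phosphorylation median was -0.071. The Nppb call was lost without the exercise array numbered 3 and without the salt array numbered 2 or 3, each leaving 0 calls. Quantile normalization, no filter, no intensity trend, the replicate block and the reading of both doubly labelled arrays as exercise also gave 0, while 7 probe sets were called without the exercise or the salt array numbered 1, 4 with the GAPDH ratio as a covariate and 3 with all 24 columns.

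**Figure D3:**
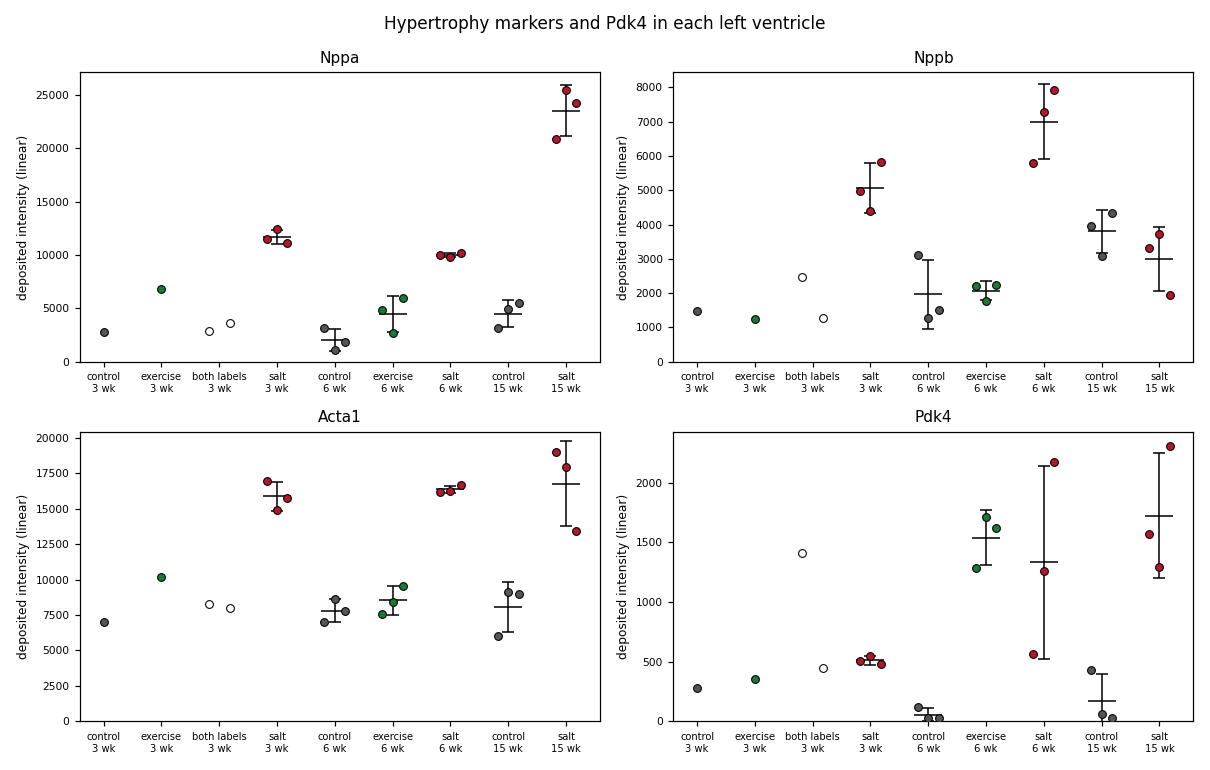
Deposited intensity (linear axes, from 0) of Nppa, Nppb, Acta1 and Pdk4 in each distinct array by group; points are arrays, bars mean ± SD for groups of 3, and open points the 2 arrays carrying both labels. Nppb averaged 6999 with high salt and 2073 with exercise at 6 weeks, while Pdk4 averaged 1332 and 1539.

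The effects of exercise and high salt at 6 weeks correlated across probe sets at r = 0.839; probe sets are not independent replicates. Both were measured against the same 3 controls. Unchanged groups simulated against those controls gave r = 0.499, with a covariance of 0.0401 where 0.262 was observed. The simulation drew all groups with the same spread per probe set and no shift of the controls. A difference of the 6-week controls shared by both effects, such as in RNA integrity, could raise r above it. Of the calls, 244 rose and 157 fell in both, where independent lists would share 19.4 and 16.9, and 0 went opposite ways. The controls could not be split into parts of at least 2 arrays, so how much of the likeness the shared controls carry was not separated further. Without the control numbered 1, r was 0.883. At 3 weeks, where both effects were measured against the same 1 control array, r was 0.460, below the 0.611 of unchanged groups simulated against it (covariance 0.0805 observed and 0.120 simulated). Effects sharing no array correlated at r = 0.270 for exercise at 6 weeks with high salt at 3 weeks and 0.350 for exercise at 6 weeks with high salt at 15 weeks. With exercise at 3 weeks r was -0.0715 for high salt at 6 weeks and 0.123 for high salt at 15 weeks. The 15-week controls also had a higher mean GAPDH ratio than their salt arrays (1.40 and 1.13). A difference in RNA integrity could therefore enter both effects of the pair at r = 0.350 without a shared array.

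At 3 weeks high salt was compared with 1 control array. Nppa was at 11674 ± 656 (n = 3) against 2806, Nppb at 5074 ± 727 against 1479, and Acta1 at 15885.5 ± 1032 against 6983. None passed over all probe sets (adjusted p = 0.19 for each). Myh6, Myh7 and Atp2a2 were at -0.097, 0.22 and -0.12 (adjusted p = 0.999 for each), and limma called 0 probe sets with 243 at an unadjusted p under 0.05. Of 15 fetal and stress genes 0 rose over all probe sets and 3 adjusted over the list alone (list adjusted p = 0.032; adjusted p = 0.14 with an estimated correlation). The red blood cell list had a median of 0.61 (adjusted p = 0.00040; adjusted p = 0.074 with an estimated correlation), and 1 of 7 rose adjusted over the list alone, Hba-a3 (1.09 ± 0.32). The matrix (median 0.22), immediate early (0.21) and atrial myocyte (0.10) lists also passed, with an adjusted p of 0.696, 0.280 and 0.280 with an estimated correlation. Igfbp2, with the smallest p (1.73 ± 0.29, adjusted p = 0.065), stood at 59.4 in that control and from 235.6 to 400.7 in every other distinct array. With both doubly labelled arrays read as controls 6 probe sets rose and 2 fell: Nppa, Nppb and Acta1 rose by 1.91 ± 0.29, 1.58 ± 0.29 and 1.03 ± 0.17, and Cbr1 fell. Read as exercise, 1 rose, for Igfbp2. Against all 4 distinct arrays of 3 weeks without salt 9 rose and 1 fell, with Nppa, Nppb and Acta1 higher by 1.62 ± 0.31, 1.68 ± 0.27 and 0.93 ± 0.16.

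Exercise at 3 weeks had 1 array against 1 control array, so the spread came from the other groups. No probe set was called by limma, with 166 at an unadjusted p under 0.05. Nppa was at 6819 against 2806 and Serpina1, a plasma protein gene of the liver, at 1165 against 184.2 (adjusted p = 0.19). Of 45 oxidative phosphorylation and citric acid cycle genes 0 fell, also 0 adjusted over the list alone, with a median of -0.13 (adjusted p = 0.0355; adjusted p = 0.866 with an estimated correlation). High salt against exercise at 3 weeks gave 1 call, Ahsg, encoding the liver plasma protein fetuin-A, which was lower with salt by -2.96 ± 0.43 (adjusted p = 0.0088) and was chosen after its values were seen. That value rests on 1 exercise array, at 6 weeks Ahsg was at -0.14 ± 0.31 (n = 3 each; adjusted p = 0.987), and the count was 0 without the 3-week salt array numbered 2. Nppb was higher by 1.98 ± 0.39 there without passing (adjusted p = 0.13), among 340 at an unadjusted p under 0.05. The matrix, red blood cell, heat shock, fetal and stress, and clock lists were higher with salt there at the preset correlation. None of them passed with an estimated correlation. With the GAPDH ratio as a covariate the fetal and stress and the clock lists did not pass, while the cell cycle list passed upward. With the readings of both arrays as controls or as exercise, 1 probe set was called in exercise against control, for Ahsg and Igfbp2 respectively.

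Over 3 and 6 weeks together, high salt raised Nppa by 2.22 ± 0.26 (adjusted p = 0.00011), Nppb by 1.83 ± 0.24, Acta1 by 1.13 ± 0.16 and Gja1 by 2.68 ± 0.40 (6 high salt and 4 control arrays). Myh6, Myh7 and Atp2a2 did not pass at their brightest probe sets (0.11, 0.37 and 0.26), while another probe set of Myh6 rose by 1.88 ± 0.37 and of Myh7 by 1.05 ± 0.25, and another of Atp2a2 fell by -0.69 ± 0.15. Aldh6a1, Cap2, Acadsb and Gpam rose by 1.69 to 1.79. Camk2n1, Cyp4b1 and Prickle2 fell by -1.48 to -1.31 and Cacna2d1, a calcium channel subunit, by -1.20 ± 0.25. In all 177 probe sets rose and 111 fell. The GAPDH ratio as a covariate left 11 calls; all 288 kept their sign, the median change in the direction of the call going from 1.01 to 0.66 and the median SE over all probe sets from 0.23 to 0.28. The count was 9 with the replicate block, 166 with only the compared groups fitted, 1049 with array weights, 691 with both arrays as controls, 567, 119 and 182 without the 6-week controls numbered 1, 2 and 3, 155, 151 and 156 without each 3-week salt array, and 132 and 123 without the 6-week salt arrays numbered 2 and 3. Of 15 fetal and stress genes 3 rose (4 rose and 2 fell adjusted over the list alone; list adjusted p = 0.0072; adjusted p = 0.0792 with an estimated correlation), with a median of 0.073 that was -0.026 with the covariate. The fatty acid oxidation (median 0.049), oxidative phosphorylation (0.086), heat shock (0.19) and atrial myocyte (-0.032) lists passed upward at the preset correlation, with an adjusted p of 0.310 to 0.643 with an estimated correlation. With the covariate, at the preset correlation, the matrix, inflammation and immediate early lists passed upward (adjusted p = 6.2e-07, 0.024 and 0.016) and the oxidative phosphorylation and glycolysis lists downward (0.011 and 0.024). Exercise over both weeks gave 0 calls by limma with 483 at an unadjusted p under 0.05, and Nppa was higher by 1.23 ± 0.30 (adjusted p = 0.31); there were 8 calls without the 6-week control numbered 1, and 1, 6 and 11 with both doubly labelled arrays as controls, as exercise and with all 24 columns. The fatty acid oxidation median was 0.15 (adjusted p = 0.0016; adjusted p = 0.881 with an estimated correlation), and -0.070 with the GAPDH ratio as a covariate. The matrix (median -0.18) and atrial myocyte (0.20) lists also passed, with an adjusted p of 0.881 and 0.740 with an estimated correlation. With the GAPDH ratio as a covariate neither passed, and the matrix median turned to 0.13. With the covariate, at the preset correlation, the oxidative phosphorylation, sarcomere and heat shock lists passed downward (adjusted p = 3.6e-08, 0.00093 and 0.042). High salt against exercise over both weeks gave 2 calls, Nppb higher by 1.86 ± 0.24 (adjusted p = 0.0015) and Ahsg lower by -1.55 ± 0.27, the latter chosen after its values were seen. The 2 other probe sets of Ahsg were at -0.22 and -0.16. Its call over both weeks rests on the 1 exercise array of 3 weeks, since its 6-week difference, given above, was small and not called. Neither the Nppb nor the Ahsg call was kept with the replicate block. There were 6, 38 and 40 calls with both doubly labelled arrays as controls, as exercise and with all 24 columns, 21 without the 6-week salt array numbered 1, and 1 without any 1 of the 6-week exercise arrays, the 3-week salt arrays numbered 2 and 3 or the 6-week salt arrays numbered 2 and 3. The fetal and stress list was higher with salt there too (adjusted p = 2.7e-05; adjusted p = 0.0074 with an estimated correlation), with 1 of 15 past the threshold and 4 adjusted over the list alone. The matrix, oxidative phosphorylation, sarcomere, immediate early and heat shock lists were higher with salt at the preset correlation, with an adjusted p of 0.224 to 0.650 with an estimated correlation.

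The change of the high salt effect from 3 to 15 weeks was tested directly. Alox15 (4.97 ± 0.60 and 3.71 ± 0.36 at 2 probe sets), Glul, encoding glutamine synthetase (2.38 ± 0.46), Cebpb (2.25 ± 0.45) and Slc4a1 (2.19 ± 0.34) had higher effects at 15 weeks. Col3a1 (-3.18 ± 0.56), Nr1d1 (-2.997 ± 0.473), Nmrk2 (-2.65 ± 0.46), Col1a1 (-2.48 ± 0.48) and the heat shock factor gene Hsf1 (-2.15 ± 0.40) had lower ones. Another probe set of Slc4a1 (-0.29 ± 0.42) and of Hsf1 (0.23 ± 0.62) had the opposite sign. In all 5 probe sets were called with a higher and 7 with a lower effect. Nppb, whose effect was lower at 15 weeks by -2.12 ± 0.48, did not pass (adjusted p = 0.088). The matrix list was lower (median -0.53; adjusted p = 4.2e-09; adjusted p = 0.26 with an estimated correlation). The clock (-0.69) and heat shock (-0.30) lists passed downward and the antioxidant (0.22) and red blood cell (0.051) lists upward, with an adjusted p of 0.136 to 0.622 with an estimated correlation. The 3-week effect rests on 1 control array, and the count was 119 with both doubly labelled arrays as controls, 3 with the replicate block, 28 with only the compared groups fitted and 123 with array weights. It was 19, 4 and 4 without the 15-week controls numbered 1, 2 and 3, 24 and 7 without the 15-week salt arrays numbered 2 and 3, and 7 and 6 without the 3-week salt arrays numbered 1 and 3. The change of the exercise effect from 3 to 6 weeks gave 0 calls by limma with 641 at an unadjusted p under 0.05, 16 without the 6-week control numbered 1, and 38 and 84 with both doubly labelled arrays as controls and with all 24 columns. Its median over all probe sets was -0.19, and -0.04 after quantile normalization. The fatty acid oxidation list had a median of 0.54 (adjusted p = 7.1e-10; adjusted p = 0.344 with an estimated correlation) that was -0.11 with the GAPDH ratio as a covariate (adjusted p = 0.922). The oxidative phosphorylation (median 0.31) and antioxidant (0.29) lists also passed, with an adjusted p of 0.526 and 0.182 with an estimated correlation, and with the covariate the former passed downward (-0.32, adjusted p = 0.025), as the skeletal muscle list did (0.0072), and the inflammation (0.0046) and cell cycle (0.025) lists upward. The controls at 15 weeks against 3 weeks gave 0 calls by limma with 231 at an unadjusted p under 0.05, and the red blood cell list was higher at 15 weeks (median 0.46; adjusted p = 0.0080; adjusted p = 0.230 with an estimated correlation), as was the ribosomal protein list (0.16; adjusted p = 0.0379; adjusted p = 0.582 with an estimated correlation). Adding the GAPDH ratio kept both and brought the fetal and stress (adjusted p = 0.014), oxidative phosphorylation (0.012), sarcomere (0.011), ion channel (0.034), atrial myocyte (0.011) and skeletal muscle (0.030) lists upward and the matrix (0.039) and cell death (0.041) lists downward past the threshold. The readings as controls, as exercise and of all 24 columns gave 5, 1 and 1 calls.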

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

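The tests on the clock genes and the collagen genes, the count of 6-week calls kept with the GAPDH ratio and with other controls, and the use of the GAPDH ratio and of other controls, were chosen after the results were seen. The other tests on the calls against the 6-week controls and the counts over other splits of the arrays were set down before their outcomes were seen.

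The effect of high salt differed between 3 and 15 weeks, by a direct test of the difference, for 12 probe sets, where the 3-week effect rests on 1 control array. The effect at 15 weeks minus that at 3 weeks was 4.97 and 3.71 for 2 probe sets of Alox15, whose 3-week effects were 0.89 and 0.15. It was 2.38 for Glul, encoding glutamine synthetase, 2.25 for Cebpb and 2.19 for Slc4a1. It was -3.18 for Col3a1 and -2.48 for Col1a1, which had 3-week effects of 0.15 and 0.20, and -2.997 for Nr1d1, whose effect went from 0.93 to -2.07. It was -2.65 for Nmrk2, -2.15 for the heat shock factor gene Hsf1, -1.78 for Vtn and -1.66 for the unnamed probe set rc_AI179012_s_at. Control probe sets, which no comparison used, gave GAPDH 3' to 5' ratios of 1.58, 2.48 and 3.99 in the 6-week controls, above the 0.989 to 1.18 of the 16 distinct arrays outside the 6- and 15-week controls.

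Many probe sets differed from the 6-week controls with both treatments, and within the 15-week controls alone the slope of each probe set on the GAPDH ratio correlated with the exercise effect at 6 weeks at r = -0.457 across probe sets, and with the high salt effect at -0.3999, while its r with the difference between high salt and exercise was 0.0211. That slope rests on 3 arrays with ratios of 1.09, 1.52 and 1.58, so any other difference of the array at 1.09 from the rest enters it too. Against the controls of 3 and 15 weeks the called probe sets kept a median share of 0.338 of the exercise effect (0.263 to 0.416 leaving out 1 of those controls) and 0.412 of the high salt effect (0.349 to 0.483), which argues against treatment as the whole of the change. With high salt, 4 probe sets, for Acta1 (1.07 ± 0.18, 1.40 ± 0.29 with the GAPDH ratio as a covariate and 1.09 ± 0.17 against the other controls) and 3 of 4 for Nppa, stayed called both ways, which argues against RNA integrity as the whole of their change. Nppb, a marker named beforehand, was higher with high salt than with exercise at 6 weeks by 1.73 ± 0.28 (limma adjusted p = 0.030). The difference of these means does not involve the 6-week controls, against which Nppb with exercise was at 0.18 ± 0.28. That argues against RNA integrity as the whole of the Nppb change with high salt, though the call between treatments was lost under several alternatives. Low RNA integrity of the 6-week controls may account for part of the other calls. Whether treatment accounts for a part of those stays open, as it does for Pdk4 and Nr1d1 with exercise, called against the other controls and not with the covariate. Age differs between these controls and the treated arrays and stays open, and the probe sets were selected with the 6-week controls, which lowers the share kept.

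Clock genes differed between arrays, with Dbp at 545.3, 39.5 and 25.5 in the 6-week high salt arrays. Different times of collection would move Dbp and Bmal1 in opposite directions within groups; over 18 arrays their deviations had r = -0.440 (permutation p = 0.455) and rho = -0.0402 (permutation p = 0.911), and r = 0.446 without the 2 farthest arrays, so the time of day stays open. Severity of the response in each heart would set Dbp against Nppa, where r was 0.160 (permutation p = 0.247) and rho 0.304 (permutation p = 0.220). Without the 2 farthest arrays r was 0.273. The 95% interval of r over all 18 ran from -0.429 to 0.653, so that test leaves severity open. Between groups, Nppa averaged 11674 in the 3-week and 9999 in the 6-week high salt arrays, while Dbp at 3 weeks was at 1501, 1566.3 and 1116.7. For these arrays that argues against severity, as read from Nppa, as the whole of the Dbp difference. At 15 weeks of high salt Nppa averaged 23511 and Dbp was at 295, 46.8 and 144, so a part for severity stays open. Dbp and Nr1d2 moved together at r = 0.861 (permutation p = 0.00192, adjusted over 5 relations 0.0096; rho = 0.752, permutation p = 0.00385) and r = 0.613 without the 2 farthest. All tests were 2-sided, and the labels used here give no time of collection.

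Collagen genes were low at 15 weeks of high salt, with a median of -0.64 over 12 genes, 5 of which fell. With the GAPDH ratio as a covariate the median kept a share of 0.763, between the bounds set for and against RNA integrity, so that explanation stays open. The beta-actin ratio, which was not used in that test, was higher in the salt arrays (1.52 ± 0.18) than in the controls (1.32 ± 0.21). Fewer fibroblasts could lower other fibroblast genes too: 12 of them had a median of -0.44, with 1 past the threshold, a share of 0.691 of the collagen median with bootstrap bounds of 0.0994 and 0.954. The bounds came from resampling the fibroblast genes, with the collagen median held fixed. That test leaves fewer fibroblasts and lower collagen transcription open, and the latter was not tested.

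Other splits of the same arrays were counted for each comparison of at least 3 arrays per group. For exercise and for high salt against control at 6 weeks, high salt against control at 15 weeks, and high salt against exercise at 6 weeks, the 10 splits are too few for a share under 0.05. In these, the real counts of 513, 939, 469 and 1 compared with a highest other count of 1, 0, 2 and 1, and 1, 1, 1 and 2 splits gave as many. For exercise over 3 and 6 weeks all 20 splits gave at least the real count of 0, the highest being 1. For high salt against control over 3 and 6 weeks 1 of 80 splits gave 288 calls and the highest other gave 4. That share is under 0.05 and is the smallest these splits can give. The real split also sets the 6-week controls apart, so the count does not tell treatment from their RNA integrity. With the GAPDH ratio as a covariate 11 were called. For high salt against exercise over both weeks 5 of 80 splits gave at least the real count of 2, up to 7, so chance was not excluded.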

How the results depend on the processing

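The readings of the doubly labelled arrays, the GAPDH covariate, the controls of 3 and 15 weeks and the 4 arrays without salt were chosen after seeing the data; the other alternatives were planned. Counts are probe sets called, and counts close to those of the main fit are mostly not listed, so an unlisted count need not be unchanged. With quantile normalization, for example, 350 rose and 217 fell for exercise against control at 6 weeks, where 293 and 220 did in the main fit. The cause was not tested for any change below, except where fewer arrays or probe sets entered by construction. A gene was counted as reversed if its sign changed and it was called in the main fit or under the alternative. No named gene reversed in this sense under any alternative other than the covariate (19 of 363) and the other controls (12 of 156). Genes not called could change sign elsewhere. Myh6 with high salt at 3 weeks, negative in the main fit, was at 0.015 with both arrays as control. By the direction of the list test, quantile normalization reversed 3 of 56 list calls, the covariate 11, and the other controls 1 of 12; the median changed sign in 6, 19 and 2 of them. No list test turned elsewhere, but medians changed sign in 3 with array weights, 3 with the mean of probe sets per gene, 3 of 5 with all 4 arrays of 3 weeks without salt, 2 with both arrays as control, 2 with the 24 columns, 1 with the stricter filter, 1 with the replicate block, and up to 4 leaving out 1 array. The number of list calls stayed within 47 to 70.

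Quantile normalization gave 1 call for high salt against control at 3 weeks, 2 for high salt against exercise at 3 weeks and 0 at 6 weeks; against exercise the oxidative phosphorylation median was -0.071 at 6 weeks and -0.052 over 3 and 6 weeks, and that of the sarcomere list -0.023 over 3 and 6 weeks. The pseudocount of 13 and the stricter filter each gave 1 call for high salt against control at 3 weeks, 0 for high salt against exercise at 3 weeks, 1 over 3 and 6 weeks, and 1 for the controls at 15 weeks against 3 weeks. The pseudocount of 130 gave 2 for exercise against control at 3 weeks and 2 over both weeks, 5, 2 and 5 for high salt against exercise at 3 weeks, 6 weeks and both, and 2 for the change of the exercise effect. No filter gave 8 and 5 for exercise against control at 3 weeks and over both, 12, 0 and 11 for high salt against exercise at 3 weeks, 6 weeks and both, and 6 for the change of the exercise effect. Without the intensity trend there were 0 for high salt against exercise at 6 weeks and 7 for the change of the high salt effect.

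The replicate block gave 240 for exercise against control at 6 weeks, 561 and 250 for high salt at 6 and 15 weeks, 9 for high salt over 3 and 6 weeks, 0 for high salt against exercise at 3 weeks, at 6 weeks and over both, and 3 for the change of the high salt effect. Replicate numbers did not pair the arrays: over 12 pairs with the same number, deviations correlated across probe sets at r = -0.226 to 0.134. Array weights gave 3, 1720 and 64 for exercise against control at 3 weeks, 6 weeks and both, 1811 for high salt against control at 6 weeks, 9, 1036 and 1049 for high salt at 3 and 15 weeks and over 3 and 6, 9 and 51 for high salt against exercise at 3 weeks and over both, 123 and 239 for the changes of the high salt and exercise effects, and 2 for the controls. Fitting only the groups compared gave 255 for exercise against control at 6 weeks, 30, 384, 266 and 166 for high salt at 3, 6 and 15 weeks and over 3 and 6, 41, 2 and 9 for high salt against exercise at 3 weeks, 6 weeks and both, and 28 for the change of the high salt effect.

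With both arrays read as control there were 1 and 1 for exercise against control at 3 weeks and over both, 8 and 691 for high salt at 3 weeks and over both, 6 for high salt against exercise over both, 119 and 38 for the changes of the high salt and exercise effects, and 5 for the controls. Both arrays read as exercise gave 1 and 6 for exercise against control at 3 weeks and over both, 1 for high salt at 3 weeks, 0, 0 and 38 for high salt against exercise at 3 weeks, 6 weeks and both, and 1 for the controls. The 24 columns as deposited gave 772 and 11 for exercise against control at 6 weeks and over both, 9 and 807 for high salt at 3 weeks and over both, 3 and 40 for high salt against exercise at 6 weeks and over both, 145 and 84 for the changes of the high salt and exercise effects, and 1 for the controls. All 4 arrays of 3 weeks without salt gave 10 for high salt at 3 weeks.

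The GAPDH ratio as a covariate gave 0 and 13 for exercise and high salt against control at 6 weeks, 4 for high salt against exercise at 6 weeks, 11 for high salt over 3 and 6 weeks and 20 for the change of the high salt effect. With it, exercise changes at 6 weeks were -0.028 for Aldoa, 0.19 for Fstl1, -0.83 for Des, 0.66 for Col5a1, -0.28 for Pygm, -0.22 for Pdha1, -0.18 for Pln, 0.078 for Gnai2, 0.44 for Nos3, -0.18 for Hspb6, -0.075 for Hspa9, -0.41 for Prdx3, -0.0079 for Gpx1 and -0.19 for Ccng1, and high salt changes were -0.23 for Pygm, -0.040 for Pdha1, 0.094 for Nos3, -0.15 for Prdx3 and 0.069 for Bnip3l. Where the list test turned, medians were, with exercise at 6 weeks, 0.055 for matrix, -0.072 for fatty acid oxidation and -0.43 for oxidative phosphorylation; with high salt at 6 weeks, -0.31 for fatty acid oxidation, -0.31 for oxidative phosphorylation and -0.081 for sarcomere; with exercise over both weeks, 0.13 for matrix and -0.070 for fatty acid oxidation; with high salt over both weeks, -0.26 for fatty acid oxidation and -0.22 for oxidative phosphorylation; and -0.32 for oxidative phosphorylation in the change of the exercise effect. The controls of 3 and 15 weeks gave 3 for exercise and 22 for high salt at 6 weeks. Against them exercise changes were 0.13 for Pfkfb2, -0.020 for Pdha1, 0.083 for Klf4, -0.083 for Hspb6, -0.12 for Gpx1, -0.025 for Gstm2, 0.11 for Fabp4, 0.21 for Myh11 and -0.031 for Cav1, high salt changes 0.037 for Rpl27a, 0.026 for Tnnt3 and -0.22 for Cav1, and the oxidative phosphorylation median with exercise -0.077.

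Leaving out 1 array at a time gave 210 to 851 for exercise against control at 6 weeks, 456 to 1225 and 212 to 539 for high salt at 6 and 15 weeks, 0 to 8 and 119 to 567 for exercise and high salt over 3 and 6 weeks, 0 to 1, 0 to 7 and 1 to 21 for high salt against exercise at 3 weeks, 6 weeks and both, 4 to 24 and 0 to 16 for the changes of the high salt and exercise effects, and r = 0.817 to 0.883 for the likeness of the 6-week effects. A group left with 1 or 2 arrays was assumed to vary like the others. The fit of only the compared groups was not run for exercise against control at 3 weeks, nor was leaving out the only control or exercise array of 3 weeks, for lack of a second array. Dim probe sets near background carry the least precise values.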

Other observations

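The tests of these groups were planned, and the values with the GAPDH ratio as a covariate or against the controls of 3 and 15 weeks were chosen after the results were seen.

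Other gene groups moved in part. Adrb1, the beta-1 adrenergic receptor gene, rose at 6 weeks with exercise (1.32 ± 0.27) and high salt (1.03 ± 0.27), while Nos3, encoding endothelial nitric oxide synthase, fell by -1.02 ± 0.29 and -1.29 ± 0.29; with the GAPDH ratio as a covariate Nos3 was at 0.44 and 0.094 and Adrb1 at 0.52 and 0.27, and against the controls of 3 and 15 weeks Adrb1 was at 0.48 and 0.19. Of the 6-week changes named here, none was called with that covariate or against those controls. At 15 weeks of high salt Rgs4, a regulator of G protein signalling, fell by -1.61 ± 0.24, and Hsd11b1, which regenerates active glucocorticoid, rose by 1.39 ± 0.30. In the list of blood pressure and adrenergic signalling 1 of 30 rose and 3 fell with exercise at 6 weeks (1 and 7 adjusted over the list alone), 1 and 2 with high salt at 6 weeks, and 2 and 2 at 15 weeks, the last 2 pairs being equal adjusted over the list alone. Among 19 ion channel and pump genes, Kcnj8, a subunit of ATP-sensitive potassium channels, fell by -1.52 ± 0.28 at 15 weeks and Kcnq1 rose by 1.53 ± 0.50 with high salt at 6 weeks; 1 rose with exercise, 3 rose at 6 weeks of salt, and 1 rose and 1 fell at 15 weeks (2 and 1 adjusted over the list alone). Of 17 cell cycle genes, Cdkn1a, a kinase inhibitor, rose by 1.36 ± 0.39 and Top2a fell by -1.11 ± 0.28 at 15 weeks, where 1 rose and 2 fell (2 and 5 adjusted over the list alone). In the endoplasmic reticulum Hspa5 and Pdia3 fell by -1.08 ± 0.21 and -0.99 ± 0.26 at 15 weeks. The blood pressure, ion channel and cell cycle lists did not pass in these 3 comparisons, with adjusted p-values of 0.0555 to 0.975.

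Markers of other cell types included genes that fell at 6 weeks. Fabp4, of fat cells and capillary endothelium, fell by -1.24 ± 0.24 with exercise and -1.53 ± 0.24 with high salt at 6 weeks, and against the controls of 3 and 15 weeks it was at 0.11 with exercise. The fat cell list had 1 of 10 fall with exercise and 2 with high salt at 6 weeks, the same adjusted over the list alone, and medians of -0.14 and -0.16. Endothelial genes went both ways: 1 of 8 rose and 2 fell with either treatment at 6 weeks (2 and 2 adjusted over the list alone), and 1 fell at 15 weeks (4 adjusted over the list alone). Tnnt3, the fast skeletal troponin T gene, fell by -0.88 ± 0.25 and -0.82 ± 0.25, the 1 of 14 skeletal muscle genes past the threshold at 6 weeks with each treatment (1 with exercise and 0 with high salt adjusted over the list alone); against the controls of 3 and 15 weeks it was at 0.026 with high salt. Prph, a neurofilament gene, fell by -1.13 ± 0.26 with exercise and -0.93 ± 0.26 at 15 weeks of high salt, and 1 and 2 of 11 nerve and glia genes fell. The fat cell, endothelial, skeletal muscle and nerve lists did not pass in these 3 comparisons, with adjusted p-values of 0.345 to 0.975. The endothelial median with exercise was 0.078 and its mean -0.09, with the list test pointing up.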
